A study of Mus musculus with 2 samples.

How the data were processed

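The series holds 2 one-colour Affymetrix expression arrays of mouse thymocytes, 1 titled DKO and 1 titled TKO. Per the labels' protocols, lineage-negative cells were purified from thymocytes by Dynabeads-based depletion, RNA was taken with an RNeasy kit, and biotin-labelled cRNA was made from 6 ug of total RNA. The labels' growth field states that mutant thymocytes were kept in standard medium, with no time given. The deposited values are array intensity values on a linear scale, 1 per probe set, and MAS5 is named in the submitters' processing notes without a version or settings. MAS5 subtracts a local background and scales each array as a whole, and the mean of the deposited intensities after trimming 2% from each end was 497 on both arrays. Signals ran up to 48752 on the DKO-labelled array and 42296 on the TKO-labelled array. Detection calls, scan dates and scanner files were not used here. With 1 array per label any batch would coincide with the label, so no batch could be tested. The number of arrays also limits the precision.

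The arrays were grouped by their titles, and the single comparison is TKO-labelled against DKO-labelled. The series' design text and the samples' genotype field give different genotypes for these titles, so the targeted genes were looked at first and the arrays are called by their labels. Of 45037 probe sets, 34945 carried 1 gene in the platform annotation, 932 carried several, and 9160 were not listed in it and stay unnamed here. Of the probe sets with 1 gene, 99.4% were matched by Entrez ID to a RefSeq gene table of assembly GRCm38.p6, which was used for current symbols and chromosomes only. Probe sets with several genes were not used for named genes of the report. Each gene was represented by its probe set with the highest mean log2 signal, which left 18193 genes.

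The deposited signals were used as scaled by the authors. A floor was set on each array at the median signal of all probe sets (68.8 on the DKO-labelled and 71.8 on the TKO-labelled array), and signals below it were raised to it. MAS5 signals of absent transcripts are not 0, and without detection calls the floor stands in for them; it shrinks the ratios of dim genes. Genes below the floor on both arrays (6913) have no ratio, and the genes measured on 1 array alone (441 on the DKO-labelled and 523 on the TKO-labelled array) have a bound, written as at least. The log2 ratio is TKO-labelled minus DKO-labelled, and a fold is its antilog, calculated in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plotted with matplotlib 3.10.9. With 1 array per genotype no test was possible, and a fixed rule of size was used in its place: a gene is counted as higher or lower at 2-fold or more.

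A set of 23 gene lists for lymphoid stages, other blood and stromal cells, Polycomb complexes and targets, cell cycle, stress and reference genes was written before the data were examined, as were the floor, the size rule, the rule for named genes and all alternatives but 1. For each list the median log2 ratio of its measured members was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean log2 signal, which describes these 2 arrays and is no test of genotype. If lists were like random ones, 1.15 of the 23 would lie outside the central 95% by chance, and 7 lay above it and 5 below. Lists share members, so they are not independent.

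The rule for named genes took the targeted genes, the 10 largest increases and 10 largest decreases among genes measured on both arrays, the 5 largest bounds each way, up to 4 members of each list with the largest absolute log2 ratio, and any member of the B lineage, T lineage and cyclin-dependent kinase inhibitor lists. Genes with another probe set of opposite sign by over 0.5 log2, provisional gene names, Y-linked genes and Xist were left out of the 10 largest and the 5 largest bounds each way, but not out of the choice within lists. Sex-linked genes and any other gene outside the rule were chosen after their values were seen.

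The procedure was tested on simulated data made from the signals of these arrays (TKO against DKO, 11088 genes, 200 changed). It recovered 98% of genes changed by 2.83-fold and 100% of those changed by 5.66-fold, and counted 57 of 10888 unchanged genes. The changed genes were drawn only from genes well above the floor on the DKO-labelled array. Noise was Gaussian with a robust SD, without the tails of the real ratios. Recovery of dim genes and of genes near the floor was therefore not tested, and the 57 hold for this noise only. Alternatives were the median log2 ratio set to 0, quantile normalization, removal of a lowess trend (span 0.3), a floor at the 25th or 75th percentile, the mean over all probe sets of a gene, and leaving out probe sets of the _x_at and _s_at types, which can cross-hybridise. Leaving out genes on the X and Y chromosomes was added after seeing the data. A wild-type or Cre-control array with intact Ring1 was not analysed here, and 9160 probe sets without a listed gene were left out of all gene counts.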

Results

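Gene expression was measured in thymocytes of C57BL/6J mice with 2 array hybridisations, 1 titled DKO and 1 titled TKO. The cells were the lineage-marker-negative fraction left after bead depletion, and the series title calls them DN (double-negative) thymocytes. The series' design text places the contrast in Lck-Cre, a recombinase driven in T-lineage cells: both genotypes lack Cdkn2a and Ring1 (Ring1A), and floxed Rnf2 (Ring1B) meets the recombinase in the TKO cells alone. The samples' own genotype field words it differently, naming loss of Ring1A and Ring1B in DKO and added loss of Cdkn2a in TKO. Ring1 and Rnf2 are the ubiquitin ligase subunits of Polycomb repressive complex 1, so the comparison asks how expression in early thymocytes differs between these genotypes. Each genotype had 1 array, so no spread between animals or cultures exists, no p-value was computed, and higher and lower below describe these 2 arrays. The arrays had been scaled alike, with a trimmed mean signal of 497 on each. Median signals were 68.8 on the DKO-labelled array and 71.8 on the TKO-labelled array, and each median served as the floor below which a signal was not counted as measured.

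Of the 3 targeted genes, Cdkn2a differed between the arrays and Ring1 and Rnf2 did not differ by 2-fold. Cdkn2a encodes the cell-cycle inhibitors Ink4a and Arf. Its signal was 679 on the DKO-labelled array and 18.5, below the floor, on the TKO-labelled array, at least 9.47-fold lower (log2 ratio -3.24). Ring1 had signals of 133 and 147 on the DKO-labelled and TKO-labelled arrays (log2 ratio 0.15). The 2 measured probe sets of Rnf2 gave 4149 and 4384 (log2 ratio 0.08), and 1771 and 2002 (log2 ratio 0.18), in the same order, and its 3 other probe sets were below the floor on both arrays. The Cdkn2a signal on the DKO-labelled array goes against the design text, by which both genotypes are Cdkn2a null. The brightest Rnf2 probe set stood at percentile 95.6 of the DKO-labelled and 95.9 of the TKO-labelled array. This goes against the samples' own field, by which both lack Ring1B, and on the TKO-labelled array against the design text too. Ring1, lost in both genotypes by either text, was above the floor on both arrays. The similar Rnf2 signals show no loss of Rnf2 transcript in either array relative to the other. Where these probe sets lie relative to the deleted segments is not given in the sources used here, and a probe set outside a deleted segment checks nothing, so the arrays are named by their labels throughout. With a higher floor, at the 75th percentile of each array, the Cdkn2a bound shrank to a log2 ratio of -0.66.

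The arrays also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome, had a signal of 124 on the DKO-labelled array and 16502 on the TKO-labelled array, 133-fold higher. The Y-linked genes Eif2s3y, Kdm5d and Uty were measured on the DKO-labelled array at 1711, 652 and 345 and lay below the floor on the TKO-labelled array at 55.3, 30.4 and 14.7. These genes were at least 23.8-fold, 9.09-fold and 4.80-fold lower there, and a second, dimmer Uty probe set (121 to 21.2) was at least 1.69-fold lower. The Y-linked Orly lay near the floor, below it on the DKO-labelled array at 61.5 and above it on the TKO-labelled array at 81.2. The Xist, Eif2s3y, Kdm5d and Uty signals are those of male cells on the DKO-labelled array and female cells on the TKO-labelled array. The labels give no sex. Sex thus differed together with the genotype label, and this holds beside every gene group that follows.

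Across the genome the difference was mostly in 1 direction. Of 11280 genes measured on at least 1 array, 404 were at least 2-fold higher on the TKO-labelled array and 60 at least 2-fold lower, so that 87.1% of the counted genes were higher. At 4-fold the numbers were 73 and 6. In the quartile of genes with the brightest signals, 32 were at least 2-fold higher and 4 lower. Log2 signals of the 10316 genes measured on both arrays correlated across genes with Pearson r = 0.974 (genes are not independent replicates), and their median log2 ratio was -0.03. Different probe sets of one gene, measured on both arrays, gave log2 ratios with a robust SD of 0.23 (ordinary SD 0.27) over 4794 genes. Such pairs were read from the same hybridisations. The SD therefore gauges disagreement between probe sets only and holds no error between RNA preparations, hybridisations, cultures or animals. The count depended on the floor: with the 25th percentile of each array as floor it was 962 higher and 434 lower, and with the 75th it was 147 and 14. Below that higher floor on both arrays, and so without a ratio there, were 19 of the genes named below as past 2-fold, among them Cfp, Enpp6, Ngp, Dkkl1, B4galnt2, Bbc3, Pax5, Hoxa9, Csf2rb and Cdkn2b.

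The largest measured increases included several immunoglobulin and B-cell genes. Chil3, a chitinase-like lectin of myeloid cells, was 17.6-fold higher (131 to 2300), and the immunoglobulin heavy chain variable segment Ighv14-2 was 14.2-fold higher (326 to 4633). Lgr5, a receptor for R-spondins, was 12.9-fold higher (72.9 to 941), and Tjp1, a tight-junction scaffold, 9.59-fold higher (81.2 to 778). Ifi209, an interferon-inducible gene, was 8.39-fold higher, Klhl32 was 7.97-fold higher, and the kappa variable segment Igkv14-111 was 7.06-fold higher. The B-cell genes Bank1, Fcrla and Ms4a1 complete the 10 largest at 7.39-fold, 6.92-fold and 6.80-fold. Second probe sets of Ifi209 and Klhl32 gave smaller log2 ratios of 0.76 and 0.23. As the mean over all probe sets Lgr5 was at a log2 ratio of 1.40, Ifi209 at 1.91, Klhl32 at 1.09 and Fcrla at 1.85. With the floor at the 75th percentile Tjp1 and Klhl32 were under 2-fold, at 0.90 and 0.93, and Chil3 was at 2.46, Lgr5 at 1.17 and Igkv14-111 at 1.76, and Bank1 was also lower but past 2-fold.

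Some genes were measured on the TKO-labelled array alone. Reln, which encodes the secreted glycoprotein reelin, had a signal of 32.5 on the DKO-labelled array and 5846 on the TKO-labelled array, at least 84.9-fold higher. The neural transcription factor genes Pou3f3 and Insm1 were at least 16.4-fold and 8.51-fold higher, with TKO-labelled signals of 1126 and 586. Fstl1, a secreted follistatin-like protein, was at least 7.70-fold higher, and Egr2, an immediate-early transcription factor, at least 7.64-fold higher. As the mean over all probe sets Reln was at a log2 ratio of 2.49 and Pou3f3 at 1.01. These are bounds against the floor, and at the 75th-percentile floor Insm1, Fstl1 and Egr2 were under 2-fold, with log2 bounds of 0.49, 0.35 and 0.33. Their second measured probe sets, where they had them, were also at least 2-fold higher, with log2 bounds of 2.18 for Insm1, 2.23 for Fstl1 and 1.97 for Egr2.

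The largest decreases were smaller in size. Ifi202b, an interferon-inducible gene of the same family as Ifi209, was 3.26-fold lower (973 to 298), and Cfp, the complement regulator properdin, was 3.26-fold lower (397 to 122). Enpp6 was 3.14-fold lower, the neutrophil granule gene Ngp 2.92-fold lower, and Zfp593 2.84-fold lower. Dglucy and Ece1 were each 2.76-fold lower, Tcl1b3 2.67-fold, Dkkl1 2.51-fold, and Pdgfrb, a platelet-derived growth factor receptor, 2.53-fold lower from a high signal (3605 to 1423). Among genes measured on the DKO-labelled array alone, B4galnt2 followed Cdkn2a at 4.65-fold lower or more (334 to 60.0), then Pafah2 and Exoc3l4 at 2.82-fold and the mast cell protease Cma1 at 2.52-fold or more. Second probe sets of Cfp, B4galnt2 and Pdgfrb gave smaller log2 ratios of -0.80, -1.05 and -1.09, and that of Ece1 was positive at 0.34. The mean over probe sets gave log2 ratios of -0.91 for Zfp593 and -0.31 for Ece1, and without cross-hybridising probe set types Zfp593 was at -0.31. With the 75th-percentile floor Dglucy and Ece1 were at -0.09 and -0.23.

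**Figure D1:**
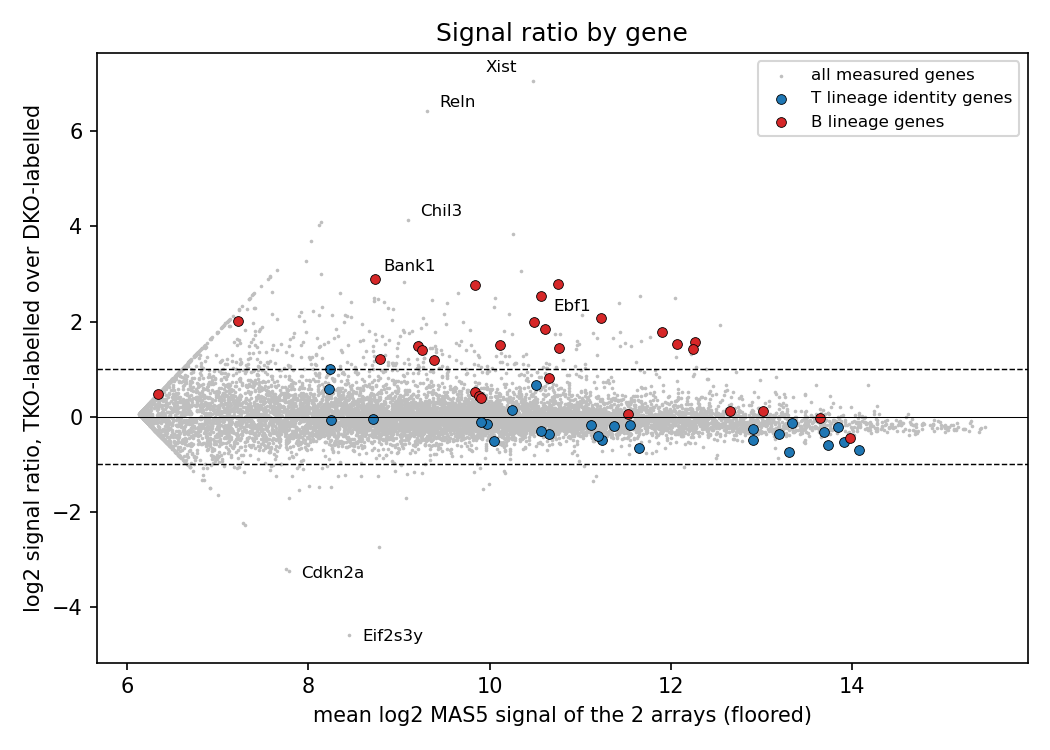
Each point is a gene measured on at least 1 array, with the mean log2 signal of the 2 arrays, floored, on the x axis and the log2 signal ratio, TKO-labelled over DKO-labelled, on the y axis. Dashed lines mark 2-fold, and of the 28 B lineage genes (red) 18 lie at or above the upper line, against 1 of the 27 T lineage identity genes (blue).

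B lineage genes were higher as a group on the TKO-labelled array. Of 28 measured members of the list, 18 were at least 2-fold higher, 0 were 2-fold lower and 10 were neither, with a median log2 ratio of 1.43 (2.70-fold). Among 10000 random gene lists of the same size and signal, the central 95% of medians ran from -0.15 to 0.06, and the B lineage median exceeded all of them (percentile 100). The higher genes included the lineage-specifying transcription factors Ebf1 (630 to 3649, 5.79-fold) and Pax5 (74.1 to 299, 4.04-fold), and the 4 measured probe sets of Ebf1 lay between log2 ratios of 1.78 and 2.56, while a second Pax5 probe set was at 0.24. They also included the surface proteins Cd72 (4.24-fold) and Cd22 (3.58-fold), the adaptor Blnk (3.98-fold), the transcriptional regulators Bach2 (2053 to 7098, 3.46-fold), Spib (2.73-fold), Pou2af1 (2.67-fold) and Irf4 (2.64-fold), and the kinases Syk (2.85-fold), Btk (2.79-fold) and Blk (2.27-fold). Of the antigen receptor signalling chains, Cd79b was 2.99-fold higher (2845 to 8501) and Cd79a 2.33-fold higher (291 to 678). Vpreb3 was 2.88-fold higher.

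Other members of the list were not 2-fold higher. Vpreb1 and Igll1, which encode the surrogate light chain of pre-B cells, each had a log2 ratio of 0.12. Dntt, the terminal transferase that both early B and early T cells use, had 18810 and 13797 on the DKO-labelled and TKO-labelled arrays (log2 ratio -0.45). The brightest Ighm probe set gave 13009 and 12741 (log2 ratio -0.03), while 5 of the 8 Ighm probe sets were at least 2-fold higher. The remaining members were Irf8 (0.81), Foxo1 (0.53), Cr2 (at least 0.47), Cd37 (0.45), Bst1 (0.40) and Rhoh (0.06), all as log2 ratios. A second Cd37 probe set was past 2-fold, at 1.26. Some calls rested on the choice of probe set or floor: as the mean over all probe sets Syk had a log2 ratio of 0.94, Ebf1 1.71 and Pax5 1.18, Cr2 had 1.44 with the 25th-percentile floor, and Cd79a had 0.70 with the 75th-percentile floor.

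**Figure D2:**
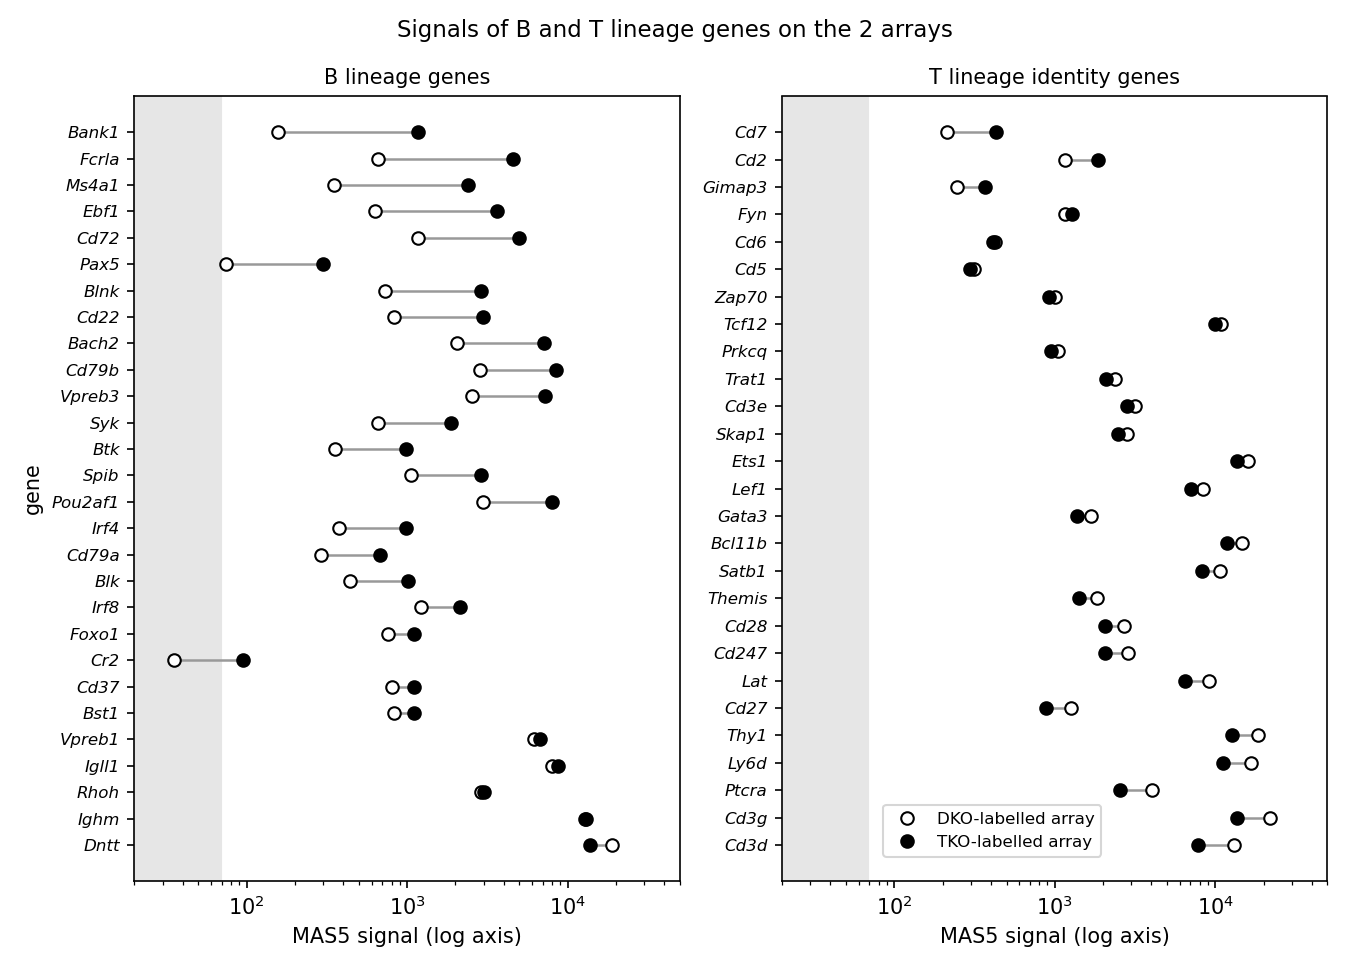
MAS5 signals (log axis) of the measured B lineage genes, left, and T lineage identity genes, right, on the DKO-labelled array (open circles) and the TKO-labelled array (filled circles), 1 array each, with a line joining the 2 signals of a gene. Grey shading marks signals below the DKO-labelled array's floor of 68.8, and 18 of 28 B lineage genes differ by at least 2-fold against 1 of 27 T lineage genes.

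T lineage identity genes were slightly lower as a group. Their median log2 ratio was -0.25 over 27 measured genes, below the central 95% of matched random lists (-0.17 to 0.02, percentile 0.01) and -0.15 after lowess (percentile 0.05), and 23 of the 27 ratios were negative. By the 2-fold rule 1 was higher, 0 were lower and 26 were neither, and 6 of the genes also stand in another list. The CD3 chains of the T cell receptor complex, Cd3d and Cd3g, had log2 ratios of -0.73 (13004 to 7822) and -0.70 (22057 to 13607), and Cd3e had -0.18. Thy1 had -0.53 (18527 to 12791), Lat -0.49 and Cd247 -0.48. The T-lineage transcription factors Bcl11b (14740 to 11799) and Gata3 (1680 to 1372) had -0.32 and -0.29, and Lef1 had -0.25. The member that passed 2-fold was Cd7, at a log2 ratio of 1.01 (213 to 430), which became 0.96 after quantile normalization. Cd2 and Gimap3 were also on the positive side, at 0.67 and 0.59.

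Genes of the Notch pathway and of the pre-T-cell receptor stage were lower in their medians. Notch1, the receptor that drives T lineage commitment, had signals of 12640 on the DKO-labelled array and 7759 on the TKO-labelled array (log2 ratio -0.70). Il2ra (CD25), a surface marker of the early double-negative stages, was lower at 6536 and 3162 (log2 ratio -1.05), and Ptcra, the pre-T-cell receptor alpha chain, had 4028 and 2564 (log2 ratio -0.65). The Notch list, of which 5 measured members stand in another list, had a median of -0.31 over 15 genes (random range -0.19 to 0.14, percentile 0.03), with 1 gene higher, 1 lower and 13 neither. The higher one was the Notch target Heyl (76.8 to 174, log2 ratio 1.18). The pre-T-cell receptor stage list had a median of -0.44 over 14 genes, below all 10000 random lists, whose central range was -0.19 to 0.08, and -0.24 as the mean over probe sets (percentile 0.35). In it Nrgn was 3.58-fold higher (167 to 597), Il2ra was lower and 12 genes were neither, among them the mast cell and progenitor protease Cpa3 at -0.88, and 10 of its members stand in another list. Il2ra lay near the limit of the rule, at -0.98 after lowess and -0.95 as the mean over probe sets. As the mean over probe sets Heyl was at 0.78, and with the 75th-percentile floor Nrgn was at 0.52.

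Early T progenitor genes were higher in their median but not alike. Their median log2 ratio was 0.51 over 17 measured genes, above all matched random lists (central range -0.18 to 0.19), with 5 genes at least 2-fold higher, 0 lower and 12 neither. The 5 were Mef2c (420 to 1666, 3.97-fold), Hoxa9 (53.9 to 249, at least 3.62-fold), Lmo2 (468 to 1656, 3.54-fold), the cytokine receptor subunit Csf2rb (142 to 424, 2.99-fold) and Hhex (762 to 1854, 2.43-fold), of which Hhex was outside the naming rule. On the other side 6 of the 17 ratios were negative, among them Nfe2 at -0.90, Runx1 at -0.65 (4901 to 3127), Erg at -0.46 and Cd34 at -0.37 or below, and Kit was at -0.08. Flt3, Meis1 and Tal1 were below the floor on both arrays. Hhex and these negative or unmeasured members were chosen after their values were seen. With the floor at the 25th percentile the median was 0.19, inside the random range (percentile 97.2). A second Hoxa9 probe set had a log2 ratio of -0.28, and as the mean over probe sets Hoxa9 was at 0.96. Genes of the later double-positive stage had a median of -0.12 over 12 genes, inside the random range (percentile 27.0), with 1 higher, 0 lower and 11 neither. The higher one was the activation marker Cd69 (230 to 462, 2.01-fold), which was under 2-fold after quantile normalization (log2 ratio 0.95) and with the 75th-percentile floor (0.15). Aqp11 had -0.69, Ly6d -0.59 and Ccr9 0.53.

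The dendritic cell list and the innate lymphoid and natural killer list had higher medians as well. The dendritic cell list, which holds the class II histocompatibility genes that B cells also express, had 7 of 14 measured genes at least 2-fold higher and 0 lower, with a median log2 ratio of 1.13 (random range -0.19 to 0.15, percentile 100). Cd74, the invariant chain of class II molecules, was 5.27-fold higher (1197 to 6305), H2-Eb1 4.41-fold (988 to 4356), H2-Aa 3.80-fold (3059 to 11611) and Ly86 3.39-fold (1224 to 4150). The other members past 2-fold, chosen after their values were seen, were H2-Ab1 (3.13-fold), the class II transactivator Ciita (at least 2.82-fold) and the chemokine receptor Ccr7 (2.52-fold). The 7 that did not pass ran from Ly6d at a log2 ratio of -0.59 to Zbtb46 at 0.94 or above, with Itgax at 0.16. The dendritic median ranged from 0.49 to 1.70 over the alternative settings and was at percentile 100 in each. In the innate lymphoid and natural killer list, 4 of 20 genes were at least 2-fold higher, 0 lower and 16 neither, with a median of 0.69 (random range -0.18 to 0.14, percentile 100). The 4 were the chemokine Xcl1 (386 to 901, 2.33-fold), the Fc receptor gamma chain Fcer1g (2.18-fold), the killer-cell receptor Klrd1 (2.12-fold) and Il18r1 (2.04-fold), the last of which was at a log2 ratio of 0.99 after quantile normalization.

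Markers of myeloid cells went both ways. Csf1r, the macrophage colony-stimulating factor receptor, was 3.23-fold higher (249 to 807), and the lysozyme genes Lyz1 and Lyz2 were 3.16-fold (1313 to 4147) and 2.49-fold (855 to 2131) higher. The neutrophil genes Ngp and S100a9 were 2.92-fold and 2.24-fold lower, and S100a9 (860 to 384) was chosen after its values were seen. The list had 3 genes higher, 2 lower and 11 neither, 8 of its 16 ratios being positive and 8 negative, with a median log2 ratio of 0.14 at percentile 84.8. That median was 0.27 at percentile 97.7 with the 25th-percentile floor and 0.48 at percentile 99.8 with the 75th, both above the random range. Csf1r was at 0.95 with the 75th-percentile floor. As the mean over probe sets Lyz1 was at 0.72. Gamma-delta T cell genes had a median of 0.03 over 10 genes (percentile 79.6), which was -0.10 with either other floor, with Blk higher, 0 genes lower and 9 neither, and the gamma chain variable segment Trgv4 had 12568 and 6859 (log2 ratio -0.87). Erythroid genes had a median of -0.16 over 5 measured genes (percentile 14.0), none past 2-fold, with Hbb-b2 at -0.43 and Hemgn at -0.42. In the thymic stroma and fibroblast list 12 of 22 genes were below the floor on both arrays. Its 10 measured genes had a median of 0.34 (percentile 99.6), with 0 higher, 1 lower (Pdgfrb) and 9 neither, among them Vim at 0.53 and Krt8 at 0.42. That median was -0.26 with the 75th-percentile floor, and it was inside the random range with the 25th-percentile floor (0.31, percentile 97.3) and as the mean over probe sets (0.16, percentile 91.4).

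**Figure D3:**
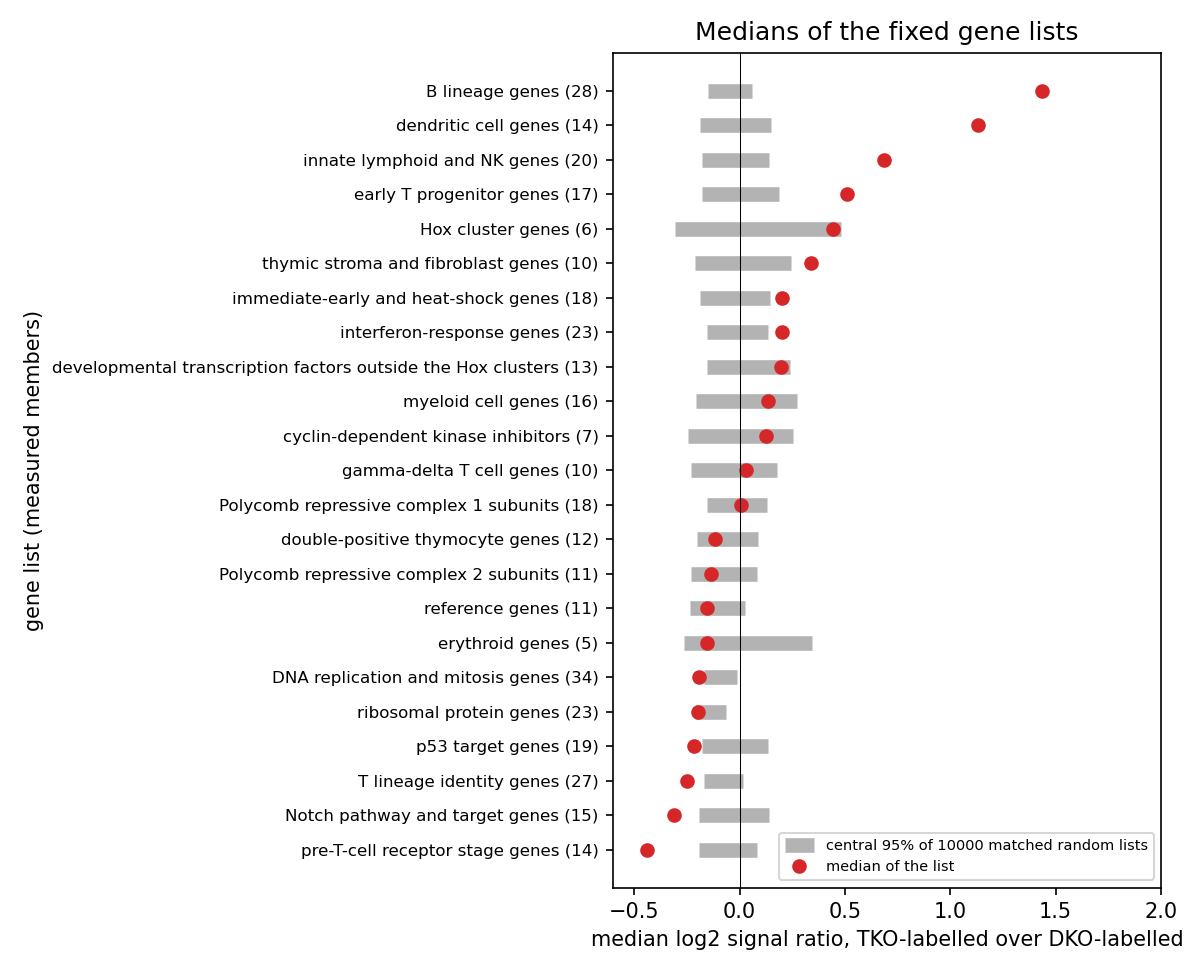
Median log2 signal ratio, TKO-labelled over DKO-labelled, of each fixed gene list (red points, with the number of measured members in parentheses) against the central 95% of 10000 random lists matched on size and signal (grey bars). Of the 23 lists, 7 lie above their bar and 5 below, and the B lineage list at 1.43 lies farthest above; the ribosomal protein and reference lists, below 0 here, had medians of 0.00 and 0.02 after lowess.

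Genes that Polycomb complexes are known to repress in other cells were mostly below the floor on both arrays. Of 39 Hox cluster genes, 33 had a usable probe set, of which 27 were below the floor on both arrays and 6 were measured. Of 77 developmental transcription factors outside the Hox clusters, 71 had a usable probe set, of which 58 were below the floor on both arrays and 13 were measured. The 6 measured Hox genes were Hoxa9 and 5 that did not pass 2-fold, including Hoxb4 at a log2 ratio of 0.89 (second probe set -0.32), Hoxa7 at 0.50 and Hoxa5 at 0.39, which was 1.36 without the _x_at and _s_at probe sets. The Hox median was 0.44, inside the random range of -0.31 to 0.48 (percentile 96.5). Among the other developmental factors Eya1 was 6.71-fold higher (69.0 to 463) and Lhx2 3.50-fold higher (303 to 1060), 0 were lower and 11 were neither, with a median of 0.20 (percentile 93.6). Without X- and Y-linked genes the median of these factors was 0.30 (percentile 99.0), above the random range. The Hox median ranged from 0.10 (percentile 59.3) with the 25th-percentile floor to 0.89 (percentile 99.6) without the _x_at and _s_at probe sets. As the mean over probe sets the Hox and developmental factor medians were 0.69 (percentile 97.9) and 0.55 (percentile 99.9), and Eya1 itself was at 0.82 as the mean over probe sets and 0.15 with the 75th-percentile floor.

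The cyclin-dependent kinase inhibitors differed little apart from the gene next to Cdkn2a. Cdkn2b, the neighbour of Cdkn2a in the genome, had a signal of 21.9 on the DKO-labelled array and 260 on the TKO-labelled array, at least 3.77-fold higher, opposite in direction to Cdkn2a. The other 6 were under 2-fold, at log2 ratios of 0.35 for Cdkn3, 0.28 for Cdkn2d, -0.22 for Cdkn1a, 0.13 for Cdkn1c, 0.07 for Cdkn1b and -0.06 for Cdkn2c. The list's median was 0.13 (percentile 89.3), and 0.23 as the mean over probe sets (percentile 98.3). None of the measured subunits of the Polycomb complexes passed 2-fold by its chosen probe set in the main setting. The 18 measured Polycomb repressive complex 1 genes had a median of 0.01 (percentile 63.6), which was below 0 in some settings (lowest -0.09), with Cbx8 at 0.98 (148 to 291; 1.01 with the median of all genes set to 0) and Bmi1 at 0.47, and the 11 Polycomb repressive complex 2 genes had a median of -0.14 (percentile 28.3), with Mtf2 at -0.33 and Phf19 at -0.28.

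Proliferation genes were nearly level between the arrays. None of 34 DNA replication and mitosis genes passed 2-fold in the main setting, and their median log2 ratio was -0.19, just below the random range of -0.17 to -0.01 (percentile 0.38). Top2a had -0.40, Mcm6 -0.38, Tk1 -0.36 and Ccne2 0.37. The median was -0.11 after lowess, and as the mean over probe sets it was -0.14, inside the range (percentile 5.98), where Mcm6 was at -1.63. Targets of p53 had a median of -0.22 over 19 genes (percentile 0.58), with the apoptosis gene Bbc3 2.36-fold lower (347 to 147), Gadd45a 2.16-fold higher (183 to 395) and 17 neither. Psrc1 stood just short of 2-fold at 1314 and 657, and past it after quantile normalization (log2 ratio -1.02).

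Interferon-response genes and immediate-early and heat-shock genes were slightly higher as groups. The interferon list had a median log2 ratio of 0.20 over 23 genes (percentile 99.6), with the chemokine Cxcl10 2.26-fold higher (94.8 to 214), Mx2 at least 2.26-fold higher, 0 lower and 21 neither. The immediate-early and heat-shock list had a median of 0.20 over 18 genes (percentile 99.3), with Egr2, Zfp36 (271 to 785, 2.89-fold) and Egr3 (134 to 294, 2.20-fold) higher, 0 lower and 15 neither. The log2 ratio of Zfp36 was 0.91 with the 75th-percentile floor, and that of Egr3 was 0.16 as the mean over probe sets, its second probe set being at -0.81. Ribosomal protein genes and reference genes, at medians of -0.20 (23 genes, percentile 6.78) and -0.15 (11 genes, percentile 32.4), were inside their random ranges with no gene past 2-fold, and after lowess both medians were no longer below 0 (0.00 and 0.02). Rps6 had -0.79, the largest departure among the ribosomal protein genes, and Pgk1 had -0.29 among the reference genes.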

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

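The alternative without X- and Y-linked genes was chosen only after the results were seen, and the others were planned. No paired analysis was possible because each genotype had 1 array. In all 8 alternatives more genes were higher than lower, the B lineage median stayed above all random lists and the T lineage median stayed at percentile 0.05 or less. Counts moved by more than 1.5 times with the floor alone, to 962 higher and 434 lower at the 25th percentile and 147 and 14 at the 75th, where by construction more or fewer genes were measured (15873 and 7191). The B lineage median was 1.49 after lowess, 1.33 at the 75th-percentile floor and 1.25 as the mean over probe sets. The T lineage median was -0.18 after quantile normalization, -0.15 after lowess and -0.31 at the 75th-percentile floor, and the cause of these shifts was not tested. Among lists outside their random range 1 median changed sign, that of thymic stroma and fibroblast genes, from 0.34 to -0.26 at the 75th-percentile floor, and the cause was not tested. Of lists inside their range, the Polycomb repressive complex 1, gamma-delta, ribosomal protein and reference medians also crossed 0 in at least 1 setting. Of 188 list medians under alternatives, 144 moved by less than the spread of random lists. The 74 named genes past 2-fold kept their sign in all of their 493 alternative values. This was largely set in advance, since a change of floor resizes such ratios without turning them. The largest increases, decreases and bounds had also been chosen without strongly opposing probe sets. The floor at the 75th percentile put 14 of the 74 under 2-fold and the mean over probe sets 9. No value could be had for 19 of the 74 at that floor, 2 as the mean over probe sets and 4 without the _x_at and _s_at probe sets. Signal over background limits dim genes most: in the dimmest quartile of genes the central 95% of log2 ratios ran from -0.82 to 1.30, and in the brightest from -0.45 to 0.66.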

Other observations

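The tests of explanations in this part, and the genes it names outside the fixed lists, were chosen only after the results were seen, while the scalings and gene lists they draw on were planned. Other immunoglobulin transcripts, apart from probe sets shared by several genes, went both ways, and some of them are given here. The lambda variable gene Iglv1 was at least 32.6-fold higher on the TKO-labelled array by 1 probe set (43.1 to 2245) and 2.02-fold and 2.05-fold higher by 2 others. Among kappa segments, Igkv8-30 was at 14657 and 23365, Igkv4-68 had a log2 ratio of 0.65, Igkv6-14 had -0.24 and Igkv15-103 had -0.54. A further kappa segment had 1.42 by 1 probe set and -0.54 by another. Igha was at 15113 and 13451. Ighg3 was lower, at 670 and 284. On the T cell receptor side, all 3 probe sets of the gamma segment Trgv4 were lower, with log2 ratios of -1.13, -0.87 and -0.44, and Trgv1 had -0.54. The beta segments were lower, with log2 ratios of -0.45 and -0.29 for Trbv1 and -0.57 for Trbv13-2. The variable alpha gene Trav9d-3 had positive ratios of 0.72, 0.87 and 0.89.

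The following are values of single genes, with no test of a family. The R-spondin receptor Lgr4 was 4.39-fold higher (146 to 643) beside the 12.9-fold of Lgr5, and Lgr6 was at least 2.83-fold higher by 1 probe set and under 2-fold by another (log2 bound 0.13). H2-Ob was 6.03-fold higher (327 to 1974), H2-DMb2 3.26-fold (285 to 930) and the lysosomal protease Ctss 2.80-fold (1810 to 5063). In the interferon-inducible Ifi200 family, Ifi202b was 3.26-fold lower while Ifi209 was 8.39-fold higher by its brighter probe set, Ifi213 had a log2 ratio of 0.91 and Ifi203 had -0.02.

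B lineage genes were higher on the TKO-labelled array, with a median log2 ratio of 1.43. Of 14 other measured probe sets of the higher genes, 92.9% had the same sign, whatever their size. All measured probe sets of Ebf1, Ms4a1, Cd22 and Bach2 were past 2-fold, which argues against cross-hybridisation for these genes. Other probe sets were under 2-fold for Pax5 (log2 ratio 0.24), Irf4 (0.48), Fcrla (lowest 0.92) and Syk (lowest -0.10). Higher genes with 1 measured probe set could not be checked in this way. Admixture of B cells, which depletion of lineage-positive cells would be meant to remove, cannot be told apart from B lineage expression in the purified cells. The T lineage median of -0.25 would be a dilution of 15.9%, or 10.6% against the median of random lists and 10.1% after lowess. The T lineage ratios spread more widely (quartile range 0.36) than those of matched genes (0.29). Even dilution of every member would not widen the spread. Admixed cells that express some members of the T lineage list could widen it, which was not tested. The spread therefore does not decide for or against admixture. Cd79b (2845 to 8501) and Cd74 (1197 to 6305) were higher on the TKO-labelled array, while Vpreb1 and Igll1 were each at a log2 ratio of 0.12. Vpreb1 and Igll1 are genes of pre-B cells, so their level signals do not bear on admixture of later B cells. Genotype and the difference in sex between the arrays also stay open as causes, and neither was tested.

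Cdkn2a was measured on the DKO-labelled array and was below the floor on the other. Its log2 ratio of -3.24 lies outside the central 95% of its signal quartile, which begins at -0.82, and its signal on the TKO-labelled array was 18.5. These values restate the pattern, and they would bear on genotype only if the probe set lay inside the deleted segment, which is not given. The same null allele on both arrays, and an exchange of the labels under the genotypes in the samples' own field, therefore both stay open. An exchange under the genotypes of the design text was not tested.

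More genes were higher than lower on the TKO-labelled array. Scaling is argued against, since the lowest share of higher genes over the 4 scalings was 83.2%. Noise of dim probe sets is argued against only for the brightest quartile of genes, where 32 were higher and 4 lower (88.9% higher). Most counted genes lie outside that quartile, and for them such noise was not tested. With the 25th-percentile floor, which admits dimmer genes, the share of higher genes was 68.9% (962 higher and 434 lower). Genes on the sex chromosomes are argued against by their share of the higher genes, 3.96% (16 of 404) against 3.15% of all measured genes. Cells of other types, an effect of sex on autosomal genes, a difference between single animals or cultures and the genotype may each contribute, and 1 array per genotype cannot separate them. As a hypothesis, loss of a repressor could give such an excess, but only under the genotypes of the design text. Under the samples' own genotype field both arrays lack Ring1A and Ring1B and would not differ in them. The brightest Rnf2 probe set, of unknown place relative to the deleted segment, gave 4149 on the DKO-labelled and 4384 on the TKO-labelled array. No wild-type array was analysed here, and the hypothesis was not tested.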
